A study of Papio anubis with 40 samples.

How the data were processed

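Circulating tRNA fragments were measured in 0.5 mL of serum per draw from 8 olive baboons (Papio anubis), drawn before inoculation (month 0) and at months 3, 6, 9 and 15. Per the labels, RNA was extracted with a magnetic-bead total RNA kit, samples with an RNA integrity number of 7 or greater were used, adapters were ligated to both ends, molecular identifiers were assigned at cDNA synthesis, and libraries were sequenced on a NovaSeq X. The deposited table gives counts per distinct fragment sequence and library, as whole numbers with no scaling. A second deposited table gives the fragment sequences, a text column that holds no other measurement. The aligner, the tRNA reference and the mismatches allowed are not given in the sources used here. R 4.5.0, edgeR and limma are named by the authors, with no role stated. Whether counts were collapsed by molecular identifier is not stated either, so the floor of 3 counts and the Wilson intervals at 95% cover counting error only.

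Of 60201 lines in the table, 1614 had no fragment ID, and each of these held an unread base. They made up 0.0805% of counts and were left out. The remaining 58587 fragments, of 16 to 89 nt, included 24658 with a total count of 1. All 40 sample columns matched the series. The table names no parent tRNA, so families were read from the sequences: the anticodon was read in fragments of at least 42 nt, fragments within 2 mismatches of its first 31 bases took that family, and an anticodon was kept with at least 2 reads and 5% of the reads behind a family. Other fragments, such as 3' and internal ones, took a family only as an exact part of a longer fragment that begins at the mature 5' end. Only 25 fragments, with 184 counts, ran the full length of a tRNA, so 3' CCA fragments of some tRNAs may have stayed unassigned. These steps gave 29 families with a read anticodon that held 99.5% of counts. Anticodons AAC and CAC of valine could not be separated for most fragments, nor initiator from elongator methionine. The Lys-TTT family rests on 8 anticodon reads, Arg-TCT and Ala-CGC/TGC on 5 each, and Cys-GCA and Leu-CAG on 2 each. Fragments were classed as 5' (starting within 2 bases of the mature 5' end), 3' CCA (ending in the bases CCA), full length, or internal and other. Whether a final CCA is that of the mature 3' end was not checked. The last class, called internal below for short, can also hold 3' pieces that lack the final base.

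Differences between months were tested with edgeR 4.0.16 in R 4.3.3: fragments kept by filterByExpr with a minimum count of 10 (2447 fragments), TMM scaling, a robust quasi-likelihood fit to all 40 libraries with animal as a block and month as a factor, and Benjamini-Hochberg adjustment over the fragments, with an adjusted p under 0.05 taken as passing. All tests were two-sided. Each later month and their mean were compared with month 0, and month 15 with month 3. All month terms were also tested jointly, which asks whether any months differ, from month 0 or from one another. Comparisons of month 15 with months 6 and 9 and among months 3, 6 and 9 were added after the data were seen, as were sums per family, which stand in for sums per parent tRNA. In deviations from month means, libraries of the same animal correlated at a mean of 0.187, against -0.0247 for libraries of different animals, and 53 of 80 same-animal pairs were above 0.1. The biological coefficient of variation was 0.500 with the block and 0.587 without.

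Library measures were compared between months with exact two-sided sign-flip tests over the 8 animals, adjusted over 44 tests. Fragment lists were tested with camera of limma 3.58.1 with an estimated correlation, adjusted over 24 tests. The lists were 5' fragments of tRNAs known to be abundant in serum, 5' fragments described as dependent on sex hormones, 5' fragments with a run of guanines, fragments described to bind YBX1, glycine tRNAs and 3' CCA fragments. Lists for leucine 3' fragments, initiator methionine, selenocysteine and mitochondrial tRNAs had 0 members among the families as read and were not analysed here. This does not show that such fragments are absent: mitochondrial tRNA sequences were not used here, so mitochondrial fragments were not looked for and can be among the unassigned ones. Markers of blood cell types are micro-RNAs, which the table does not list. Tests, lists and the rule for named fragments were chosen before the data were examined, except where stated.

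Named fragments were, for each later month and for the mean against month 0, those that passed and had the same sign in at least 7 of 8 animals, the most abundant per family and class, up to 10 with the largest change in each direction. Where fewer than 3 passed, the 5 with the smallest p were named as not passing. The 10 most abundant fragments, the families that passed and the 3 most abundant members of each list were named as well. CPM values are counts scaled to a common library total after multiplying each total by its TMM factor, and SDs are over 8 animals. Floors in CPM and shares of counts use the plain totals.

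Alternatives tried were RLE size factors (DESeq2 1.42.0), library totals as the only scaling, no filter and a stricter filter, no block, DESeq2 and limma-voom with animal as a random effect in place of edgeR, an adjusted p under 0.10, log10 library total as a term, only the 2 months compared, and leaving out each animal. Added after the data were seen were limma-voom with library weights, leaving out the PA8001 library of month 0, the month 15 libraries of PA8001 and PA8003 or these 3, each pair of month 15 libraries, and mean fragment length as a term. Also added then were leaving out each animal for the measures chosen after the data were seen, leaving out the library in which an abundant fragment is highest, and matching 3' CCA to 5' fragments nt by nt. For lists, a preset correlation of 0.01, fry and a fit without the block were tried. The months were permuted within animals in 100 splits, the real one included.

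The steps were tested on simulated data: negative binomial counts drawn from the fitted means per animal, the library totals and the spread of the real fragments, with 200 fragments changed at month 15. With the block, edgeR recovered 25% of fragments changed 2-fold and 82% of those changed 4-fold, with 2.73% false calls; without it, 14% and 74%. DESeq2 recovered 35% and 87% with 7.58% false calls, and limma-voom 21% and 80% with 0.980%. Sums per family recovered 5 of 5 families raised 4-fold with a set spread, among 34, and called 3 others, which can hold some of the 200 changed fragments. None of 20 random lists passed. Each fragment was drawn independently, so no simulated library stood apart as a whole. These rates therefore do not carry over to real libraries that do. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, exact tests and plots.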

Results

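Serum was drawn from 8 olive baboons before menstrual tissue was placed in the peritoneal cavity at laparoscopy, a procedure that induces endometriosis in this species, and again at months 3, 6, 9 and 15. Small RNA from each draw was sequenced, and tRNA fragments, the cleavage products of transfer RNAs, were counted by sequence. The 40 libraries, 8 per month, ask how circulating fragments differed from each animal's own month 0. No animal went without inoculation, so a difference between months can also follow age or anything else that changed between the draws. Library totals ran from 198840 counts (PA8001, month 0) to 6245450 (PA8914, month 9). The monthly means were 3455727 ± 1870784 (SD, n = 8) at month 0 and 2676934 ± 783006 at month 15. A count of 3, the limit that a count of 0 allows, equalled 0.480 to 15.1 CPM (counts on the scale of a common library total) depending on the library.

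Serum held almost only 5' fragments, those that begin within 2 bases of the mature 5' end of the tRNA. They made up 99.2% of the 130892201 counts, against 0.0733% for fragments that end in CCA, the triplet added to the 3' end of every mature tRNA, and 0.772% for internal and other fragments. Fragments of the valine tRNAs with anticodon AAC or CAC took 41.9% of counts, Gly-CCC 40.5%, Glu-CTC 6.05%, Lys-TTT 4.90% and Gly-GCC 3.98%. In the fragment names the first number is the length in nucleotides (nt). The most abundant fragment was tRF-31-79MP9P9NH57SD of Val-AAC/CAC, at a mean of 199324 CPM over the 40 libraries. It was followed by the Gly-CCC fragments tRF-27-Q1Q89P9L842 (121178 CPM), tRF-29-Q1Q89P9L84FS (93673 CPM) and tRF-32-Q1Q89P9L8422Q (89929.5 CPM). The last of these stood at 1051136 CPM after scaling in PA8003 at month 15, and without that library its mean was 65283 CPM, below the 71385 to 74902 CPM of tRF-30-Q1Q89P9L8422 without and with its own highest library. The 10 most abundant fragments held 73.9% ± 2.63 (SD, n = 8) of the counts at month 0 and 73.4% ± 4.71 at month 15. None of these 10 passed at any later month by edgeR; the smallest adjusted p at month 15 was 0.117, for tRF-32-Q1Q89P9L8422Q (log2 1.00 ± 0.346 SE, higher in 6 of 8 animals).

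At months 3, 6 and 9 no fragment passed the test against month 0. At month 3 the 5 smallest p-values belonged to the Met-CAT fragment tRF-30-FPR8LPMBQ4NK (log2 1.17 ± 0.346 SE, higher in 8 of 8 animals), the Glu-TTC fragment tRF-32-86J88PMN1E8YN (log2 -1.15, lower in 8), tRF-42-96L85DMKYUYRLHR0J of Asp-GTC (log2 1.79), tRF-37-79MP9P9NH57S362 of Val-AAC/CAC (log2 2.60) and tRF-56-PSQP4PW3FJIKE7UMKKSWRND of Lys-CTT (log2 1.42), each with an adjusted p of 0.999. At month 6 they belonged to tRF-16-W3FJIKB of Lys-CTT (log2 -1.86), tRF-30-P4R8ZP9LON4V of Gly-GCC (log2 0.95 ± 0.253 SE, higher in 7 of 8), tRF-31-79MP9PMMH57SD of Val-AAC/CAC (log2 0.86), tRF-42-1OR6QO004MR1J5KUF of no assigned tRNA (log2 -2.73) and tRF-56-PSQP4PW3FJI0E7UM8KSWRND of Lys-CTT (log2 1.48), each with an adjusted p of 0.303. At month 9 the smallest adjusted p was 0.329, for tRF-43-96L85DMKYOYRLHR0D2, a 3' CCA fragment of no assigned tRNA (log2 1.85 ± 0.432 SE, higher in 8 of 8). The next 4 had an adjusted p of 0.582: tRF-36-S2P46INO86RM7KE of Lys-CTT (log2 -2.01), the Asp-GTC 3' CCA fragment tRF-42-S5QKF1R3WE8RO86J2 (log2 1.17, higher in 8 of 8), tRF-32-Q1QK9P9L8422Q of Gly-CCC (log2 -1.41, lower in 8) and tRF-32-86J88PMN1E8YN again (log2 -1.24, lower in 8). Beside these counts of 0 by edgeR over 2447 fragments stood 73, 310 and 201 fragments with an unadjusted p under 0.05 at months 3, 6 and 9. DESeq2 called 0, 17 and 0, and limma-voom 0 each; limma-voom with library weights called 1 at month 9, and edgeR without a filter on low counts called 8 each at months 6 and 9. Of the fragments named for month 3, tRF-42-96L85DMKYUYRLHR0J and tRF-37-79MP9P9NH57S362 had month 0 means of 0.410 and 0.428 CPM. Both means lie under the floor of 3 counts in each month 0 library (0.542 to 15.1 CPM), so the sizes of their changes are uncertain.

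At month 15, 54 fragments rose and 4 fell against month 0, and most of those that rose were assigned to 1 tRNA. Of the 54, 3 had no assigned tRNA, all of them 3' CCA fragments. Fragments of Asp-GTC made up 36 of the 54: 15 that end in CCA, 26 to 45 nt long, and 21 internal ones, 20 to 42 nt long. Length variants of 1 fragment are not independent, and the estimated correlation among the 3' CCA fragments was 0.371. Counts of fragments, here and below, are therefore not counts of separate observations. All 28 tested 3' CCA fragments of Asp-GTC were higher at month 15 (median log2 1.43), as were 67 of its 82 internal ones (median log2 1.26), under each of the 3 scalings. The 22 tested 5' fragments of Asp-GTC had a median log2 of 0.14 with none called, and the sum of all fragments of the family had a log2 of 0.11 ± 0.300 (SE, adjusted p 0.802). Most Asp-GTC counts lay outside the 5' class (82.6% at month 0). In a test added later, the log2 ratio of its 3'-side to its 5' fragments was higher by 0.12 ± 0.891 (SD, 4 of 8 animals, exact sign-flip p = 0.742). No rise was thus seen in the family's counts as a whole. The 5' fragments that rose were mostly long: 9 of the 10 had at least 32 nt. They came from Lys-CTT, Val-AAC/CAC, Glu-CTC, Gly-CCC, Gly-GCC and Lys-TTT. The 4 that fell were 3 Gly-CCC 5' fragments of 26 or 27 nt and a Glu-CTC fragment of 20 nt.

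Of the 58, 51 had the same sign in at least 7 of 8 animals, and 10 higher and 2 lower ones, each the most abundant of its family and class, are named here. Among these 12 the largest change was in tRF-25-MBQ4NKKQBR of Met-CAT, from 0.788 ± 0.999 CPM at month 0 to 5.23 ± 4.79 (SD, n = 8) at month 15 (log2 2.29 ± 0.603 SE, adjusted p 0.0395). Its month 0 mean lies near the floor of 3 counts, which was 0.542 to 15.1 CPM in the month 0 libraries, so the size of this change is uncertain. Higher in 8 of 8 animals were tRF-56-PSQP4PW3FJI0E7UM8KSWRND of Lys-CTT (log2 2.21 ± 0.473, adjusted p 0.0204) and tRF-36-87R8WP9N1EWJQ7D of Glu-CTC, which went from 19.8 ± 14.4 to 81.2 ± 68.3 CPM (log2 1.86 ± 0.513, adjusted p 0.0443). Higher in 7 of 8 were tRF-36-79MP9P9NH57S3UD of Val-AAC/CAC (log2 2.05), tRF-19-1SS2P4IR of Lys-CTT (1.97), tRF-19-PE6LQFK4 of Arg-TCT (1.92), tRF-32-P4R84P9LON4V3 of Gly-GCC (1.87), the unassigned 3' CCA fragment tRF-40-2VR008R9D9KUMKF6 (1.82), tRF-32-PYRP4PW3FJHP1 of Lys-TTT (1.77) and tRF-34-M2OSRNLNKSEKH9 of Asp-GTC (1.70 ± 0.441, adjusted p 0.0370). The most abundant 3' CCA fragment, tRF-42-S5QKF1R3WE8RO86J2 of Asp-GTC, rose from 47.8 ± 33.0 to 101.1 ± 67.6 CPM (log2 1.17 ± 0.322, adjusted p 0.0443). The next, tRF-41-8HM2OSRNLNKSEK51B, did not pass (log2 1.48, adjusted p 0.0683), and tRF-40-2VR008R959KUMKF6 did (log2 1.34, adjusted p 0.0495, higher in 6 of 8); both are of Asp-GTC. Among lower fragments, tRF-27-E1Q89P9L842 of Gly-CCC went from 1247 ± 536 to 563 ± 233 CPM (log2 -1.18 ± 0.293, adjusted p 0.0355, lower in 7 of 8), and tRF-20-WP9N1EWJ of Glu-CTC had a log2 of -1.33 ± 0.373 (adjusted p 0.0495, lower in 7 of 8).

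The month 15 count, from the edgeR fit with animal as a block, rested on few libraries. The month 15 libraries of PA8001 and PA8003 stood apart from the others, and without both no fragment passed (216 with an unadjusted p under 0.05, against 509 with all libraries); the median log2 of the Asp-GTC 3' CCA fragments was then 1.30 and that of the internal ones 0.79. The PA8001 library of month 0, which has the lowest total, also stood apart, and 19 passed without it. Leaving out 1 animal at a time gave 12 without PA8001, 3 without PA8003, 7 without PA8873, 9 without PA8912 and 0 without PA8914. DESeq2 called 151, including all 58, and limma-voom 53, of which 40 were among the 58; limma-voom with library weights called 17. Without a filter on low counts 53 passed, but only 11 of them were among the 58. Without the block 69 passed, with 37 among the 58. With library totals as the only scaling 5 passed, and a fit to the libraries of months 0 and 15 alone called 0.

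**Figure D1:**
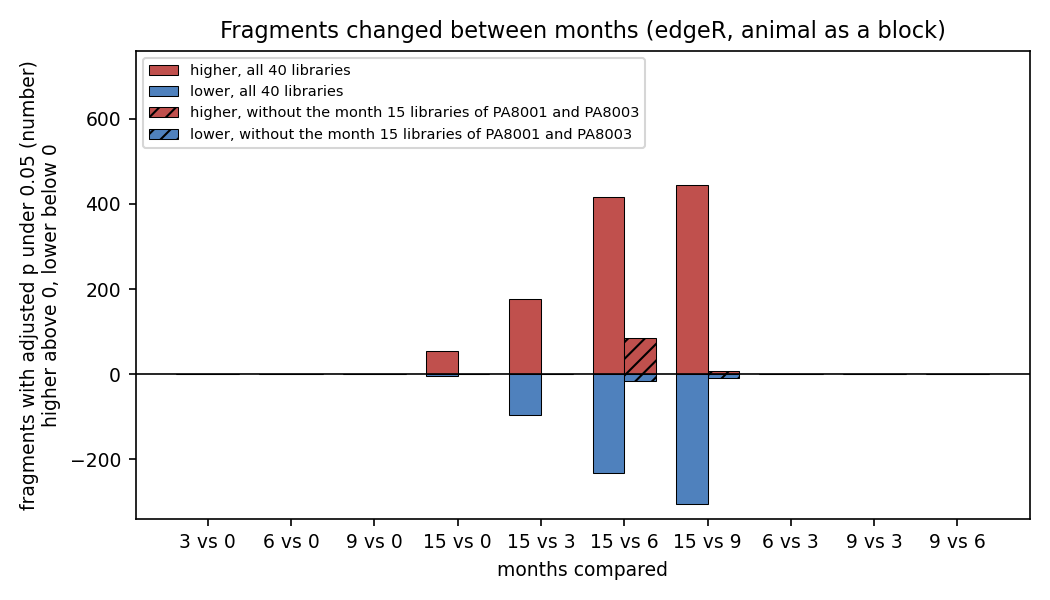
Number of fragments with an adjusted p under 0.05 in each comparison of months, higher above 0 and lower below 0, from the edgeR fit to all 40 libraries (plain bars) and to the 38 left without the month 15 libraries of PA8001 and PA8003 (hatched bars). With all libraries, 58 fragments passed for months 15 and 0 and 749 for months 15 and 9, and no comparison among months 0 to 9 has a bar.

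**Figure D2:**
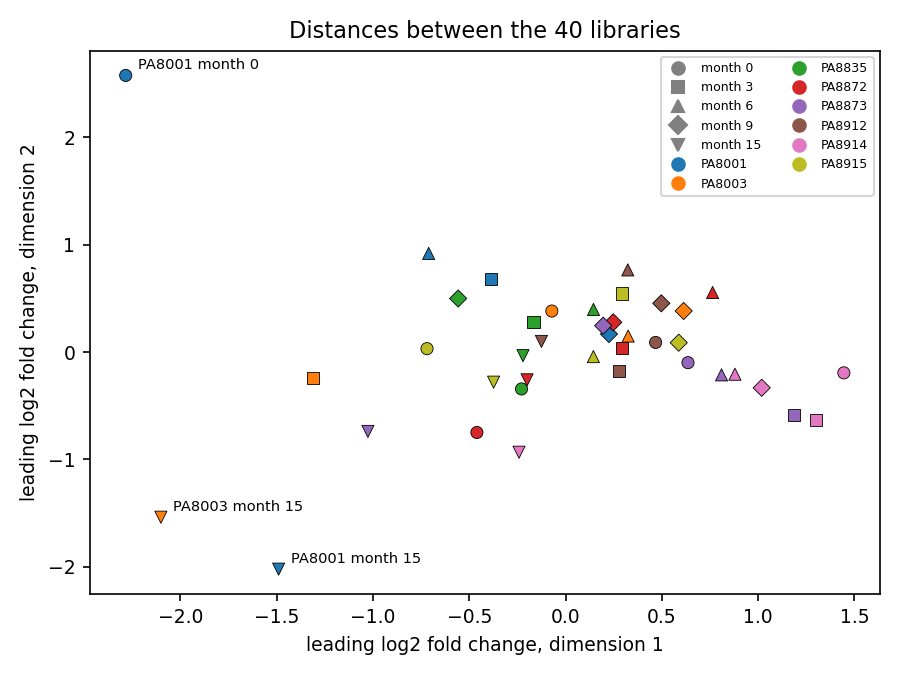
Distances between the 40 libraries, in which both axes are leading log2 fold changes of a multidimensional scaling, symbols give the month and colors the animal. The libraries of PA8001 at months 0 and 15 and of PA8003 at month 15 lie apart from the rest, with median Spearman correlations to the other libraries of 0.637, 0.628 and 0.646 against 0.764 to 0.876.

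The 5' fragments of 26 to 36 nt parted by length at month 15: 469 of the 511 of 32 to 36 nt were higher than at month 0 (median log2 0.60), and 449 of the 1352 of 26 to 31 nt were (median log2 -0.19). At months 3, 6 and 9 the medians of the longer group were -0.15, -0.27 and -0.37, and those of the shorter group 0.17, 0.13 and 0.15. These signs were alike under each scaling. Without the month 15 libraries of PA8001 and PA8003 the 2 medians at month 15 were 0.43 and -0.11. Still shorter 5' fragments did not follow this order. At month 15 their medians lay above 0 at each length from 16 to 25 nt except 19 nt (-0.24). At 24 nt the median was 0.79 (11 of 12 higher) and at 25 nt 0.57 (20 of 21 higher). These lengths held 6 to 35 tested fragments each. Mean fragment length per library went from 30.2 ± 0.356 nt at month 0 to 30.5 ± 0.349 nt (SD, n = 8) at month 15, longer in 8 of 8 animals (exact sign-flip p = 0.00781, the smallest that 8 animals can give). The share of counts in 25 to 29 nt went from 28.3% ± 7.11 to 21.3% ± 6.23, lower in 7 of 8 animals (exact p = 0.0156), and that in 30 to 36 nt from 70.9% ± 7.14 to 77.6% ± 6.06 (exact p = 0.0156). The share of 3' CCA fragments went from 0.0701% ± 0.0476 to 0.156% ± 0.0922, higher in 7 of 8 (exact p = 0.0234). None of the 44 tests of library measures passed after adjustment; the smallest adjusted p was 0.229, and with 8 animals at least 7 tests would have to reach the smallest p for any to pass.

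**Figure D3:**
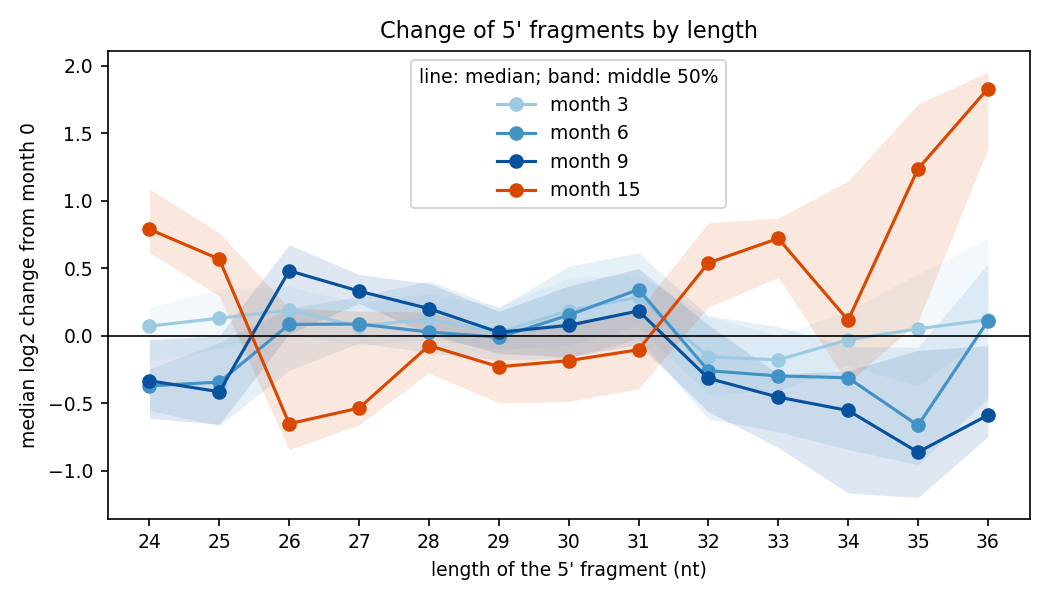
Median log2 change from month 0 of the tested 5' fragments of each length from 24 to 36 nt, with bands for the middle 50% of fragments and a line per month. At month 15 the median lies at -0.65 for 26 nt and 0.54 for 32 nt, with the same signs under the scalings tried for the ranges of 26 to 31 and 32 to 36 nt, while at months 3, 6 and 9 the medians at 32 nt lie below 0. At month 15 the medians at 24 and 25 nt, 0.79 and 0.57, also lie above 0.

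The joint test of all later months asks whether any months differ, from month 0 or from one another. By it 397 fragments passed, with 791 at an unadjusted p under 0.05, and this is not a count of changes against month 0 alone. The mean of months 3 to 15 differed from month 0 for no fragment by edgeR, DESeq2 or limma-voom, with 121 fragments at an unadjusted p under 0.05 by edgeR, and without the filter edgeR called 1. The 5 smallest p-values of that mean belonged to tRF-43-96L85DMKYOYRLHR0D2 (log2 1.56, adjusted p 0.412), tRF-42-S5QKF1R3WE8RO86J2 (log2 0.98, adjusted p 0.502), tRF-56-PSQP4PW3FJI0E7UM8KSWRND (log2 1.44), tRF-42-96L85DMKYUYRLHR0J (log2 1.74) and tRF-33-Q1Q89P9L84220P of Gly-CCC (log2 -1.38). The 397 also depended on the 2 month 15 libraries of PA8001 and PA8003, since 0 passed without them. The count was 264 without animal PA8001, 32 without PA8003, 219 without PA8872, 100 without PA8873, 260 without PA8912 and 124 without PA8914, and 127 with library totals alone. Without a filter 507 passed, of which 127 were among the 397.

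Against the draws after inoculation, month 15 differed in more fragments than against month 0. Against month 3, a comparison planned beforehand, 176 fragments rose and 96 fell; against months 6 and 9, compared after the data were seen, 417 rose and 233 fell, and 445 rose and 304 fell. Among the called 5' fragments, nearly all long ones rose and short ones mostly fell. Of the 525 tested with at least 32 nt, 121 of 121 called ones were higher at month 15 than at month 3, 182 of 184 than at month 6 and 249 of 250 than at month 9. Of the 1497 tested with at most 31 nt, of which 1352 have 26 to 31 nt, 80 of 94, 206 of 302 and 240 of 321 called ones were lower. Most of both groups were not called. By family, all called Lys-TTT 5' fragments rose (33, 65 and 58), and Val-AAC/CAC 5' fragments mostly fell (48 of 51, 118 of 138 and 116 of 160); the medians of both families kept their sign under each scaling in these comparisons. Months 3, 6 and 9 did not differ from one another in any fragment by edgeR, DESeq2 or limma-voom; at an unadjusted p under 0.05 edgeR had 44 fragments for months 6 and 3, 56 for months 9 and 3 and 49 for months 9 and 6. Of the 58 fragments called against month 0, 23 were called against all other months. The median log2 of all fragments was 0.10 at month 3 against month 0 and -0.11 at month 15 against month 3, while with library totals alone both lay within 0.01 of 0, so changes that involve month 3 are relative to a shift of that size.

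These counts, too, fell without the month 15 libraries of PA8001 and PA8003, to 0 against month 3, 99 against month 6 and 16 against month 9. Against month 3 the count was 175 without PA8001, 23 without PA8003, 165 without PA8872, 0 without PA8873, 172 without PA8912, 0 without PA8914 and 116 without PA8915. Against month 6 it was 310 without PA8003, and against month 9 it was 444 without PA8001 and 189 without PA8003.

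Counts summed over all fragments of a tRNA family gave 42 families, of which 1 rose at month 15. Arg-TCT went from 29.4 ± 24.05 to 67.5 ± 39.4 CPM (SD, n = 8), with a log2 of 1.54 ± 0.440 (SE), an adjusted p of 0.0445 and 7 of 8 animals higher. Most of its counts are of tRF-19-PE6LQFK4, the fragment of 19 nt named above, which went from 19.8 ± 16.6 to 56.6 ± 41.3 CPM, so the family adds little to that fragment. By the joint test of all later months, which also covers differences among them, 4 families passed: Arg-TCT (adjusted p 0.0142), a family beginning with GACGAGGTGGCCGA whose anticodon was not read (0.0142), Val-AAC/CAC (0.0166) and Val-TAC (0.0353). Val-AAC/CAC had log2 values of 0.38, 0.96, 0.54 and -0.38 at months 3, 6, 9 and 15, and Val-TAC 0.13, 0.55, 0.45 and -0.55. At months 3, 6 and 9 edgeR, DESeq2 and limma-voom called 0 families, with 0, 6 and 3 at an unadjusted p under 0.05 by edgeR. At month 15 DESeq2 called 1 and limma-voom 0, with 5 at an unadjusted p under 0.05. The Arg-TCT call ended with library weights, no block, a stricter filter, only the 2 months compared or a depth term. It also ended without PA8001, PA8873, PA8912 or PA8914 (0 families each) and without the 2 month 15 libraries of PA8001 and PA8003. Its log2 was then 1.26, 1.46, 1.67 and 1.35 without these animals and 1.18 without the 2 libraries. Over all later months 1 family was called without PA8001, PA8003 or PA8835 and 2 without PA8914, and at month 9 1 was called without PA8873.

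Of the 6 fragment lists fixed before the data were examined and tested at each later month, none passed after adjustment over 24 tests with an estimated correlation (smallest adjusted p 0.309). The 3' CCA list came closest at month 15: 51 of its 53 members were higher (median log2 1.39, against 0.03 for other fragments; p = 0.0146 with an estimated correlation), 18 rose over all fragments tested and 31 when adjusted over the list alone. The 18 are 15 fragments of Asp-GTC and 3 of no assigned tRNA. At month 9 the list had 0 calls over all fragments and 2 when adjusted over the list alone. Fragments of the tRNAs described to bind YBX1, an RNA-binding protein, had 40 calls at month 15 (39 higher) and 56 when adjusted over the list alone (52 higher), but only 264 of 512 members were higher (p = 0.825 with an estimated correlation); 36 of the 40 were of Asp-GTC. The 1617 5' fragments of tRNAs known to be abundant in serum had 12 calls at month 15, 9 of them higher, and 0 when adjusted over the list alone (p = 0.0258 with an estimated correlation, lower than other fragments; median log2 -0.01, mean 0.06).

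Glycine tRNA fragments had 6 calls at month 15, 3 of them higher, and 0 when adjusted over the list alone (423 of 835 higher; p = 0.599 with an estimated correlation). The 5' fragments of Asp-GTC, His-GTG and Lys-CTT, described as dependent on sex hormones, had 2 calls, both higher, and 2 when adjusted over the list alone (p = 0.869 with an estimated correlation). Their 3 most abundant members were all of Lys-CTT: tRF-32-PSQP4PW3FJI01 (log2 0.51 at month 15), tRF-31-PSQP4PW3FJI0B (-0.27) and tRF-31-PSQP4PW3FJIKB (-0.38). The 5' fragments of alanine and cysteine tRNAs that begin with a run of guanines had 0 calls by edgeR, over all fragments and when adjusted over the list alone (10 of 21 higher, median log2 -0.07, mean 0.13; p = 0.715 with an estimated correlation). Their families rest on 5 anticodon reads for alanine and 2 for cysteine. With a preset correlation of 0.01, 6 of the 24 tests passed: 3' CCA fragments at months 3, 9 and 15, glycine fragments at months 3 and 6, and the serum 5' fragments at month 15. None of these 6 held with the estimated correlation, where their p-values were 0.398, 0.246, 0.0146, 0.125, 0.239 and 0.0258. By fry, which asks whether a list's members move, on balance, one way, the 3' CCA list at month 15 passed alone (adjusted p 0.00270).

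**Figure D4:**
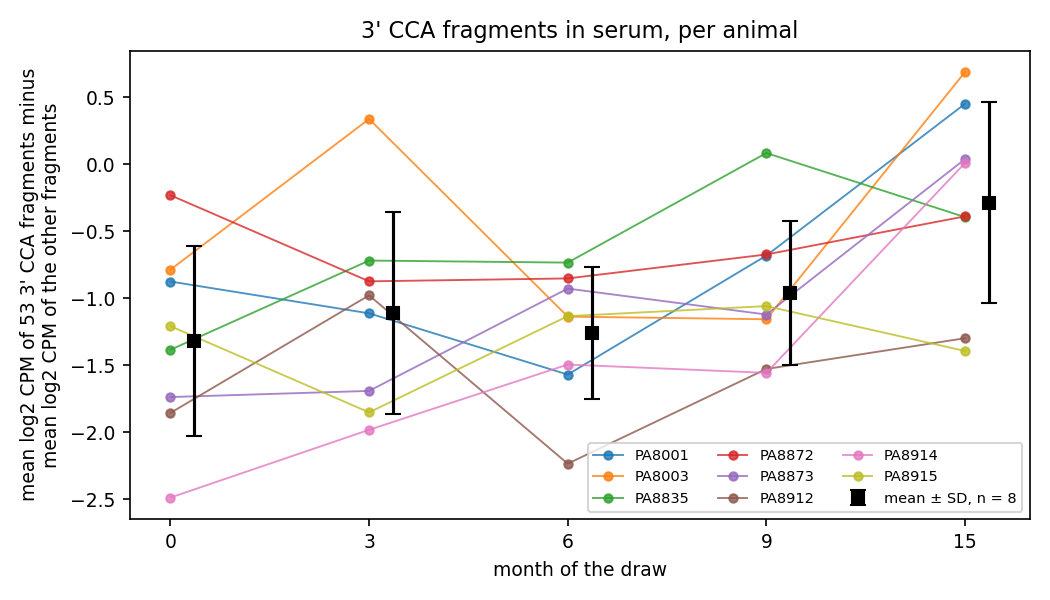
Mean log2 CPM of the 53 tested 3' CCA fragments minus the mean of the other fragments, per animal (lines) and as mean ± SD of 8 animals (squares), against the month of the draw. From month 0 to month 15 the difference went up by 1.04 ± 0.934 (SD, n = 8) on the log2 scale, in 6 of 8 animals, and the list stayed higher at month 15 under the 3 scalings tried.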

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

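The tests of the month 15 calls against single libraries were chosen only after the result was seen; the term for library depth was planned, but its criterion and those of the splits of the samples were written after. The match of 3' CCA fragments nt by nt and their division into Asp-GTC and others were chosen after the first results were seen. The other tests of fragment length and of the 3' CCA fragments were planned before their results, though for patterns already seen in these data. Of 68 groups of 8 values, 14 held a library far from the others, where chance gives about 1 in 20 such groups if they are independent and normally distributed. Several of these measures are related shares of the same library, so the 14 cannot be set directly against that rate. The PA8001 library of month 0 had 2281 fragments detected, against 7360 to 10488 in the other animals. At month 15, PA8001 had the lowest share of 5' fragments (97.7%, interval 97.68 to 97.72, others 98.9 to 99.4) and the highest share of internal and other fragments (1.95%, interval 1.93 to 1.97, others 0.510 to 0.952). The latter share was also highest in PA8001 at month 9 (1.33%, interval 1.32 to 1.35, others 0.564 to 0.840). PA8003 at month 15 had 83.9% (interval 83.84 to 83.91) of counts in its 10 most abundant fragments, against 69.0 to 75.6 in the others. At month 3 PA8003 had the highest shares of 3' CCA fragments (0.221%, interval 0.214 to 0.229, others 0.0278 to 0.116) and of fragments over 36 nt (0.271%, interval 0.263 to 0.279, others 0.0359 to 0.139). At month 9 PA8835 had the highest shares of 3' CCA fragments (0.270%, interval 0.260 to 0.281, others 0.0351 to 0.0900), of fragments over 36 nt (0.238%, interval 0.228 to 0.249, others 0.0446 to 0.112) and of fragments of at most 24 nt (1.02%, interval 1.003 to 1.04, others 0.474 to 0.669). PA8872 at month 0 had the highest share over 36 nt (0.264%, interval 0.257 to 0.270, others 0.0197 to 0.134), and PA8873 at month 6 the lowest 5' share (98.9%, interval 98.86 to 98.88, others 99.2 to 99.4). Intervals are Wilson intervals at 95% and cover counting error only.

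Among named fragments, the change from month 0 to month 15 of tRF-32-PYRP4PW3FJHP1 (Lys-TTT) was log2 5.14 in PA8003 against -0.25 to 2.20 in the other animals, and that of tRF-40-2VR008R9D9KUMKF6 was -1.62 in PA8915 against 0.60 to 2.48. The effects at months 15 and 3 differed in 272 fragments by the direct test of the difference, among them 8 named ones. The log2 difference was 1.93 for tRF-36-79MP9P9NH57S3UD, 1.82 for tRF-32-PYRP4PW3FJHP1, 1.81 for tRF-19-1SS2P4IR, 1.75 for tRF-32-P4R84P9LON4V3, 1.71 for tRF-25-MBQ4NKKQBR, 1.71 for tRF-34-M2OSRNLNKSEKH9, -1.09 for tRF-20-WP9N1EWJ and -0.89 for tRF-27-E1Q89P9L842. Sequences with an unread base and no fragment ID, used in no comparison, held 0.0805% of all counts.

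The 58 fragments called at month 15 against month 0 are set here against 3 technical explanations. A trend with library depth over all libraries as the whole cause is argued against, since 56 of the 58 stayed called with log10 library total as a term. That term cannot settle the part of the 1 shallowest library, PA8001 at month 0, whose floor of 3 counts was 15.1 CPM. Without this library 18 of the 58 stayed called, which also removes a sample, so its part stays open. The month 15 libraries of PA8001 and PA8003 may carry much of the count: without both, 0 fragments were called and 216 had an unadjusted p under 0.05, and 0 of the other 27 pairs of month 15 libraries left as few (259 to 755), although 5 of those pairs also left 0 calls. With mean fragment length of the library as a term 0 calls stayed, the outcome written beforehand for length as the cause. The median log2 of the 54 higher calls went from 1.91 (median SE 0.492) to 1.52 (0.511), and all 58 kept an unadjusted p under 0.05. Length may thus carry part of the change, and as the whole cause it stays open. The weight given to the size of the change was decided after that value was seen. Disease and age stay open and untested, since every animal was inoculated and aged alike.

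For the 3' CCA fragments that were higher at month 15, a general shift to longer fragments as the whole cause is argued against for the 15 of the 53 that have 25 to 36 nt, and stays open for the others. The rise was picked from these same libraries, where the list test at month 15 did not pass (adjusted p 0.309 by camera). The p-values below are therefore no separate support for a rise. The 15 rose over 1884 5' fragments of the same range by a mean log2 of 1.09 ± 0.828 (SD, n = 8), higher in 7 of 8 animals (exact sign-flip p = 0.0156, adjusted p 0.0365), but 7 of the 15 and only 511 of the 1884 have at least 32 nt, so length acts within that range. Set against the 5' fragments of exactly its own length, the mean was 0.72 (-0.22 to 1.91 over the animals, higher in 7 of 8, exact p = 0.0156, adjusted p 0.0352 over 9 tests) and 0.55 to 0.86 when 1 animal was left out (exact p at most 0.0313); without PA8001 and PA8003 the values were 0.90 and 0.76 (5 of 6 each, exact p = 0.0625 each) and neither passed. Over all fragments that are not 3' CCA, the 28 of Asp-GTC rose by 1.19 ± 0.821 (SD, 7 of 8, exact p = 0.0156, adjusted p 0.0365). The 25 others had a mean of 0.86 ± 1.18 (-0.99 to 2.36 over the animals, higher in 6 of 8, exact p = 0.0859) and did not pass. Asp-GTC was singled out from the calls in these same libraries, so its p is no separate support. The 28 and the 25 were not compared directly, so a difference between them is not shown. Whether the pattern needs the month 15 libraries of PA8001 and PA8003 cannot be told apart from a loss of power: over the 6 other animals the mean log2 difference of 3' CCA from all other fragments was 0.91, higher in 4 of 6 (exact p = 0.125), against 1.04 over 8 animals (exact p = 0.0313, adjusted p 0.0547), and a biological cause may exist but was not separated from time by this design.

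In 100 splits that permuted the months within animals, the real one included, no other gave as many calls for any month (real 397, highest other 198). The same held for month 15 against months 3, 6 and 9 (real 272, 650 and 749, highest other 159, 278 and 183). Of these, the comparisons with months 6 and 9 were chosen after the data were seen. As 1 in 100 is the smallest share these splits can give, this argues against chance but cannot exclude it. By fragments at an unadjusted p under 0.05, however, another split passed month 15 against month 3 (851 against 793) and 1 came near any month (776 against 791). For month 15 against month 0, 2 splits gave as many calls (real 58, highest other 449). The split with 449 calls is several times the real count and points to a structure of the samples: it kept the month 15 libraries of PA8001 and PA8003 at month 15 and gave the month 0 library of PA8001 to month 6. Both month 15 libraries fell in the same month in 23 of the 99 other splits, and in 7 of the 12 that called a fragment in any planned comparison. For families, as many calls came in 3 splits at month 15 (real 1, highest other 2) and in 2 splits over all months (real 4, highest other 4). These 3 results are under the limit of 5 in 100, but in each another split equalled or passed the real count, so chance stays open for them. The splits do not speak to single libraries: without the month 15 libraries of PA8001 and PA8003 the counts for month 15 against months 0 and 3 and for any month were all 0. Where the real count was 0, all 100 splits give as many whatever the data, so they say nothing of chance: months 3, 6 and 9 and the mean against month 0 (highest other 35, 183, 6 and 292), month 6 against month 3 (44), month 9 against months 3 and 6 (1 and 58), and families at months 3, 6 and 9 (2, 2 and 8).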

How the results depend on the processing

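The settings that leave out named libraries, library weights, the length term, all settings for families and those for month 15 against months 6 and 9 were chosen after the data were seen; the others were planned. No named fragment or family that had passed changed sign under these settings. Among the added measures given below, none of which had passed, signs at month 15 did change. The Asp-GTC ratio of 3'-side to 5' fragments had either sign when 1 animal was left out at a time. The Gly-GCC ratio of 32 to 31 nt fragments went from a log2 of 0.65 to -0.02 without PA8001 and PA8003. At month 3 and among months 3, 6 and 9, all settings run gave 0. Library measures also gave 0 in each, but at least 7 tests at the smallest exact p would be needed for 1 to pass, so this says nothing of stability. Counts are by edgeR with animal as a block unless a tool is named. For month 15 against month 0 (58 fragments) the count was 151 by DESeq2, 106 at an adjusted p under 0.10, 19 without the month 0 library of PA8001, 17 by limma-voom with library weights, 5 with library totals alone, and 0 without the month 15 libraries of PA8001 and PA8003, without all 3 libraries, with only the 2 months compared and with mean fragment length as a term. Any month (397): 657 by DESeq2, 644 at 0.10, 127 with totals alone, 0 without the 2 month 15 libraries and 0 without the 3. Month 15 against month 3 (272): 581 at 0.10, 518 by DESeq2, 181 without the block, 111 without a filter, 47 with totals alone, and 0 with library weights, with only the 2 months, without the 2 libraries and without the 3. Month 15 against month 6 (650) gave 346 without a filter, 149 without the 3 libraries and 99 without the 2; against month 9 (749) it gave 381 without a filter, 359 with totals alone, 18 without the 3 and 16 without the 2. Counts of 0 turned to 17 (DESeq2) and 8 (no filter) at month 6, 8 (no filter) and 1 (library weights) at month 9, and 1 (no filter) for the mean of all later months. Lists that passed went from 0 to 6 with a preset correlation and to 1 with fry. Families at month 15 (1) became 3 without the month 0 library of PA8001, and 0 with library weights, limma-voom, no block, a stricter filter, only the 2 months, a depth term, and without the 2 or the 3 libraries. Families over all months (4) became 2 with a stricter filter, 1 with RLE size factors, 1 without the 2 libraries, and 0 without the 3 or the block; families at month 9 (0) became 2 without a filter. Leaving out 1 animal gave 0 to 77 fragments for month 15, 32 to 416 for any month, 0 to 364 against month 3, 310 to 665 against month 6 and 189 to 853 against month 9, and 1 to 5 families for any month, 0 to 1 at month 15 and 0 to 1 at month 9; for other counts of 0 it gave 0 to 0. Leaving out libraries or months also removes samples, and no filter adds fragments to the adjustment; for the other changes the cause was not tested. Of the values of named fragments and families that had passed, 109 stayed past the threshold and 198 did not, with the same sign in all; of those that had not passed, 16 came to pass. Sums per parent tRNA were not run, as the table names no parent, and only the 2 months compared has no value for any month or the mean. Depth limits fragments under 15.1 CPM in the smallest library and under 0.480 CPM in the largest.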

Other observations

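All tests in this part were chosen only after the data were seen. At month 9 the share of Asp-GTC counts outside the 5' class went from 82.6% ± 8.48 to 90.5% ± 4.26 (SD, n = 8), higher in 8 of 8 animals (exact sign-flip p = 0.00781, the smallest that 8 animals can give). The log2 ratio of its 3'-side to its 5' fragments was higher by 0.96 ± 0.683 (8 of 8 animals, exact p = 0.00781) at month 9 and by 0.12 ± 0.891 (4 of 8, exact p = 0.742) at month 15, where leaving out 1 animal gave -0.05 to 0.34. At month 9 all 28 tested 3' CCA fragments of Asp-GTC had a log2 above 0 (median 0.66) and all 22 tested 5' fragments one below 0 (median -0.88), with none called by edgeR. For Gly-CCC the same ratio was higher at month 15 by 0.93 ± 1.22 (7 of 8, exact p = 0.0156), by 0.55 without PA8001 (6 of 7, exact p = 0.0313) and by 0.64 without PA8001 and PA8003 (6 of 6, exact p = 0.0313). At an equal depth of 198840 counts, 2492 ± 325 fragments were expected at month 0 and 2974 ± 632 at month 15, a mean difference of 481 (7 of 8 animals, exact p = 0.0469). Without PA8001 this difference was 281 (6 of 7, exact p = 0.0938), and without PA8001 and PA8003 it was 358 (6 of 6, exact p = 0.0313). None of the 64 tests of these added measures passed after adjustment, with a smallest adjusted p of 0.111, and more than 10 tests at the smallest exact p would be needed for any to pass.

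A hypothesis for the length pattern is that the 3' end of 5' fragments may lie 1 nt later at month 15 within each tRNA, read as a higher ratio of 32 to 31 nt fragments in each of 7 families. The log2 ratio was higher than at month 0 by 0.51 ± 0.314 (SD, n = 8) for Val-AAC/CAC (8 of 8 animals, exact p = 0.00781), 0.79 ± 0.871 for Lys-CTT (7 of 8, exact p = 0.0156) and 1.06 ± 1.28 for Glu-TTC (7 of 8, exact p = 0.0703). It was higher by 0.65 ± 1.56 for Gly-GCC (5 of 8, exact p = 0.297), 0.56 ± 1.06 for Lys-TTT (5 of 8, exact p = 0.172), 0.38 ± 0.722 for Gly-CCC (5 of 8, exact p = 0.188) and 0.57 ± 1.29 for Glu-CTC (4 of 8, exact p = 0.273). Over the 6 animals other than PA8001 and PA8003 the values were 0.38 for Val-AAC/CAC (6 of 6, exact p = 0.0313), 0.53 for Lys-CTT (5 of 6), 0.80 for Glu-TTC (5 of 6), 0.55 for Lys-TTT (4 of 6), 0.31 for Gly-CCC (4 of 6), 0.45 for Glu-CTC (3 of 6) and -0.02 for Gly-GCC (3 of 6). Without PA8003 alone they were 0.52 for Lys-CTT, 0.38 for Gly-GCC, 0.33 for Lys-TTT, 0.27 for Glu-CTC and 0.20 for Gly-CCC. Gly-GCC was also 0.34 without PA8001 and 0.97 without PA8872, and Glu-CTC 0.36 without PA8914. Adjusted over the 64 tests, the smallest p of the 7 families was 0.111, so the hypothesis stays open.

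Over all 5' fragments the same ratio was lower at months 6 and 9 by log2 values of -0.86 and -0.75 (7 of 8 animals lower, exact p = 0.0156 each) and higher at month 15 by 0.74 (5 of 8, exact p = 0.109). Without PA8001 the value at month 9 was -0.43, and without PA8003 the value at month 15 was 0.36.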
